A study of Mus musculus with 2 samples.

How the data were processed

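DNase-seq maps open chromatin: nuclei are treated with the nuclease DNase I, which cuts accessible DNA first, and the cut ends are sequenced. The data came from liver of mouse embryos at embryonic day 11.5, pooled over both sexes, of the strain B6NCrl. Per the labels, both libraries are technical replicates of biological replicate 1 and share 1 biosample, numbered technical replicate 7 and technical replicate 1. There is therefore 1 biological sample, no second group and no comparison between conditions. No p-value across samples was computed, and intervals cover counting error only, not the spread between animals. The labels name 2 sequencing instruments for technical replicate 7 and none for technical replicate 1, so a difference of sequencing batch between the libraries is open.

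Per the labels, coordinates are on the mouse assembly mm10. The aligner, the peak caller and the footprint caller are not given in the sources used here. The peak lists were called by the authors on each library separately. For every peak the deposited lists give a signal, the highest density of DNase cuts, besides a density at the summit and a smoothed height. The deposited hotspots, broader regions of raised cutting, carry a −log10 value of the false discovery rate. The deposited footprints, short protected stretches inside open regions, carry a constant value of 0.01 in technical replicate 1, read as a p-value or FDR threshold. The deposited hotspots of an earlier processing of technical replicate 1 carry a score. A further deposited file of technical replicate 1 lists single positions with an FDR below 0.05.

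Each library had 2 peak lists of alike format, and the shorter was an exact subset of the longer in both. The accompanying notes state no thresholds. The hotspots under the shorter lists reached down to a −log10 value of 3 and those under the longer lists to 2 in both libraries, so the shorter lists were taken as the stricter, at an apparent FDR of 0.001, and were used throughout. This reading comes from the values. A peak given as absent from a library is absent from the list used, unless other lists are named. For footprints, the shorter of 2 lists of technical replicate 7 was used; technical replicate 1 had 1 list, from a different processing, so footprint numbers are not comparable between the libraries.

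The densities fell on whole multiples of 1 step in each library, within a tolerance of 0.02 steps for 100% of the values under 2. The step was 0.00401 in technical replicate 7 and 0.0101 in technical replicate 1, a ratio of 2.52. If 1 step stands for 1 cut and densities are scaled to M cuts (10 to the power 6), which the headers do not state, the libraries hold about 249.7 M and 99.0 M cuts. Densities were used to rank peaks within a library. They are also given as values for single peaks and pile-ups, and as bar heights in the figure of loci.

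Peaks were called shared where they overlapped by at least 1 bp. Overlapping peaks of both libraries were joined into 34017 shared regions, each placed at the midpoint of its strongest peak in technical replicate 7. Overlap by chance was taken from 100 circular shifts of the peaks of technical replicate 1 along each chromosome. Shares have exact Clopper-Pearson 95% intervals. Regions were assigned to transcription starts (within 1 kb of a start of the GENCODE vM21 basic annotation), otherwise exon, intron or intergenic, beside the share of each class among sequenced bases of GRCm38, whose chromosome lengths hold every listed peak.

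Before the data were examined, 18 gene lists with 336 genes and 25 consensus motifs were fixed. Of these genes 335 were found in the annotation. For each list the number of members with a shared peak within 1 kb of a start was set against 10000 random lists of protein-coding genes matched on deciles of promoter CpG content (observed over expected in 1000 bp around the 5′ end). The mean number of distal shared peaks within 50 kb of a start, over 1 kb from any start, was set against 10000 random lists matched on quintiles of the number of protein-coding starts within 50 kb. A list is called high or low where it lies outside the central 95% of the random lists; chance puts about 5% of lists there. Such percentiles describe these libraries. The genes named are, for each list, the 3 members with the highest mean rank percentile of their strongest promoter peak over both libraries and the members with no promoter peak in either library where at most 3 lack one, plus 14 genes fixed by name, the 10 protein-coding genes with the most distal shared peaks (1 gene per 100 kb window), and the 5 distal shared regions with the highest mean density rank. Of the genes this rule takes, 2 are not reported here. Any other gene was chosen after its values were seen. Near-identical genes (the adult beta-globin pair, the adult alpha-globin pair and Serpina1a) are uncertain, since reads from them may not map uniquely.

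Motifs were searched on both strands within 75 bp of each region's centre and in equal windows 1 kb to each side that touch no peak of either library. The ratio of the shares has a 95% interval for counting error. Footprint motifs were searched in 31 bp around the footprint's centre and at the same distance from points moved by 100 bp inside the same peak and outside other footprints. Alternatives to each choice are given in the closing section. Methods were tested on simulated data with known answers. With nothing planted, 4.00% of 400 simulated lists were called for promoter peaks and 4.75% for distal peaks. A doubling of distal peaks was called in 100% of 400 lists of 25 genes, and 89.2% of 400 lists were called when 80% of their missing promoter peaks were filled. The simulated distal counts were Poisson values drawn independently for each gene. In the data 47.2% of protein-coding genes had no distal shared peak, single genes had up to 22, and neighbouring genes share peaks. The simulated rates for distal peaks may therefore not carry over, and a list within the range is not shown to lack a 2-fold excess. In 93.5% of 200 simulations the interval held a true motif ratio of 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.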

Results

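Open chromatin was profiled by DNase-seq in the liver of mouse embryos at embryonic day 11.5, when the organ holds hepatoblasts, the precursors of hepatocytes, and is a site of red blood cell formation. The series holds 2 libraries of 1 biological sample, technical replicates 7 and 1. The list of technical replicate 7 had 86036 peaks with a median width of 258 bp, covering 23.4 Mb. That of technical replicate 1 had 42422 peaks with a median width of 303.5 bp, covering 13.4 Mb. The step of the density values was 2.52 times finer in technical replicate 7, which would be its excess in depth if 1 step stands for 1 cut; the headers do not state this. With 1 biological sample no value below has a biological error.

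Almost all of the strongest peaks overlapped between the libraries, and most of the weakest peaks of technical replicate 7 were listed for it alone. Of the peaks of technical replicate 1, 89.9% (95% interval 89.7 to 90.2; 38158 of 42422) overlapped a peak of technical replicate 7, against 1.84% on average (highest 2.07%) after circular shifts. Of the peaks of technical replicate 7, 46.2% (45.9 to 46.6; 39786 of 86036) overlapped a peak of technical replicate 1. Among the weakest 10% of technical replicate 7's peaks 10.2% were shared, and among the strongest 10% 99.3%. For technical replicate 1 the corresponding shares were 77.1% and 99.8%. When the longer list was limited to the length of the shorter by density, 73.3% and 73.6% of the peaks were shared. Over the 34017 shared regions, the density ranks of the libraries had a Spearman correlation of 0.821; this runs across regions of 1 sample, and regions are not independent replicates.

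**Figure D1:**
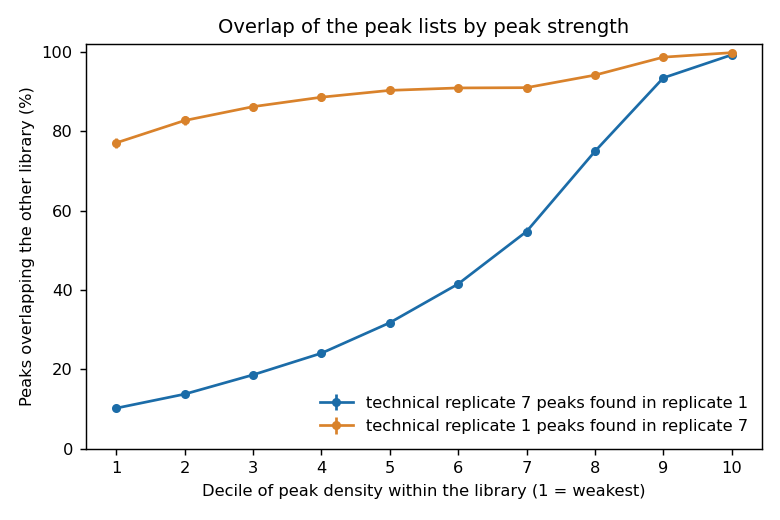
Share of peaks overlapping the other library (%, y axis) by decile of peak density within a library (x axis, 1 is the weakest), for technical replicate 7 (blue) and technical replicate 1 (orange), with 95% exact intervals for counting error. The share rose from 10.2% to 99.3% in technical replicate 7 and from 77.1% to 99.8% in technical replicate 1.

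Transcription starts were the most frequent place of shared open chromatin. Of the 34017 shared regions, 57.9% (57.4 to 58.4) were centred within 1 kb of a start, a class that covers 4.37% of the genome, a 13.2-fold excess. Introns held 20.1% of shared regions against 40.3% of the genome, intergenic sequence 18.3% against 52.5%, and exons away from starts 3.71% against 2.91%. The share at starts was 61.9% in technical replicate 1 alone and 38.4% in technical replicate 7 alone, so this value depends on the library. Peaks listed only for technical replicate 7 (46250) lay at starts in 19.6% of cases, in introns in 43.7% and between genes in 32.4%. Peaks listed only for technical replicate 1 (4264) lay at starts in 74.9% of cases. Of 21938 protein-coding genes, 12944 (59.0%) had a shared peak at a start.

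Erythroid genes had open promoters more often than genes of like CpG content at the 5′ end. Of 29 erythroid genes in the annotation, 18 (62.1%) had a shared peak at a start, against a median of 34.5% in random lists of like CpG content (95% of lists between 24.1% and 48.3%; percentile 99.995). Against random lists not matched on CpG the same count lay at percentile 62.3, so the excess holds only against genes of like CpG content. CpG content was measured at the 5′ end of the gene only, whereas a peak at any annotated start counted, as for Gata1 below. The number of starts per gene was not matched. The strongest were Tfrc, the transferrin receptor (shared peak on chromosome 16, 32608695 to 32609089; mean rank percentile 99.5 over both libraries), Zfpm1, the GATA1 cofactor FOG1 (99.3), and Fech, the last enzyme of haem synthesis (92.9). Gata1, a main regulator of red cell development, had a shared peak at a start inside the gene on chromosome X (7967732 to 7968147; mean rank percentile 30.7), and Klf1, an erythroid activator of globin genes, had one on chromosome 8 (84901003 to 84901473; 52.1). In technical replicate 7 alone 24 of the 29 genes had a peak at a start.

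Hepatoblast genes were split by library. In shared peaks 15 of 31 (48.4%) were open at a start, within the random range (median 51.6%; percentile 32.2), whereas in technical replicate 7 alone 25 of 31 were, at percentile 99.9. In the stronger 50% of shared peaks the list was low instead, at percentile 1.60. The strongest were genes for transcription factors: Foxa3 (mean rank percentile 94.5), Cebpa (87.9) and Onecut2 (84.5). Alb, the gene for albumin, had no peak at a start in either library; Afp, alpha-fetoprotein, and Hnf4a, a central hepatocyte regulator, each had 1 in technical replicate 7 and none in technical replicate 1. For Hnf4a that peak lay at the transcript start of the basic annotation, inside the gene (density 0.717), and a further peak of technical replicate 7 lay at the 5′ end of the gene (chromosome 2, 163506667 to 163506941; density 0.509), where the basic annotation has no transcript start. Genes of mature hepatocytes were mostly closed: 3 of 25, namely Gls2, Glul and Ass1, had a shared promoter peak, at percentile 2.72, inside the central 95% of random lists by a narrow margin and outside it in each library alone (0.220 in technical replicate 7, 2.38 in technical replicate 1), with a promoter window of 2500 bp (1.17) and against lists not matched on CpG (0).

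Haematopoietic progenitor, megakaryocyte, macrophage, endothelial, mesenchymal and cholangiocyte genes were within the random range in shared peaks, but each of these lists except that of cholangiocytes left it under another setting. Haematopoietic progenitor genes were open in 15 of 20 cases (percentile 87.7), led by Lyl1 (mean rank percentile 91.5), Kit, the stem cell factor receptor (86.8), and Meis1 (83.3); Cd48 had no promoter peak in either library. Megakaryocyte genes were open in 4 of 12 cases (percentile 42.2; Nbeal2, Thbs1 and Itgb3 strongest) and mesenchymal and stellate cell genes in 12 of 20 (percentile 82.2; Alcam, Col1a1 and Pdgfra). In technical replicate 7 alone these 3 lists lay higher, at percentiles 99.0, 98.6 and 98.9. Endothelial genes were open in 5 of 15 cases (percentile 11.5; Kdr, Sox17 and Flt1), cholangiocyte genes in 3 of 10 (percentile 17.1; Muc1, Sox9 and Epcam) and macrophage genes in 1 of 15 (percentile 6.55). Endothelial genes were below the range in the stronger 50% of shared peaks (percentile 0.180). Against random lists not matched on CpG, endothelial (2.495) and macrophage genes (0) were below it. Endothelial genes lay higher in technical replicate 7 alone, where 10 of 15 were open, at percentile 86.4 and within the range. Cdh5, the endothelial cadherin, and Csf1r, the macrophage growth factor receptor, had no promoter peak in either library. Spi1, which encodes the myeloid factor PU.1, had a shared one (mean rank percentile 46.0).

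Hox genes, gut and pancreas genes, germline and pluripotency genes and lymphoid genes had fewer open promoters than random lists. Hox genes, which set position along the body axis, had a shared promoter peak in 4 of 39 cases (10.3%), against a median of 82.1% in lists of like CpG content and below all 10000 of them; Hoxc10, Hoxb4 and Hoxb5 were the strongest. In technical replicate 7 alone 22 of the 39 had a promoter peak, also below all random lists. Hox genes lie in clusters, whereas the genes of random lists were drawn independently, so the random range may be too narrow for this list. Gut and pancreas genes were open in 1 of 14 cases (Nkx6-1; random median 50%) and germline and pluripotency genes in 2 of 12 (Dazl and Utf1; random median 66.7%), both below all random lists. Lymphoid genes were open in 2 of 14 cases, Ebf1 and Tcf7 (percentile 2.14), a call lost in technical replicate 7 alone at percentile 2.76, with both other promoter windows and in the stronger 50% of shared peaks (14.3). Neuronal genes were open in 10 of 18 cases (percentile 4.26; Snap25, Map2 and Isl1 strongest), striated muscle genes in 3 of 16 (percentile 5.81; Actn2, Ryr1 and Myod1) and epidermal genes in 1 of 12 (Krt10; percentile 22.1), none of them outside the range. All 3 lists fell below it under other settings: neuronal genes in the stronger 50% of shared peaks (percentile 0) and with a promoter window of 500 bp (0.08), striated muscle genes with that window (2.24) and against lists not matched on CpG (0.055), and epidermal genes against such lists (0.005). In technical replicate 7 alone neuronal genes were open in 14 of 18 cases, at percentile 54.3. Striated muscle genes were open there in 4 of 16 (3.455) and epidermal genes in 1 of 12 (8.34), so that each list lay within the range. Neurod1 had promoter peaks in technical replicate 7 only. All 20 housekeeping genes had a shared promoter peak (percentile 99.8), with Polr2a, Gapdh and Actb strongest, and so did 13 of 15 imprinted genes (percentile 98.9), with Cdkn1c, Peg3 and Igf2r strongest; in the stronger 50% of shared peaks the imprinted genes lay at percentile 37.4. Xist, the RNA of X inactivation, had 1 shared peak at a start. In all, 3 of the 18 lists were high and 4 low.

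**Figure D2:**
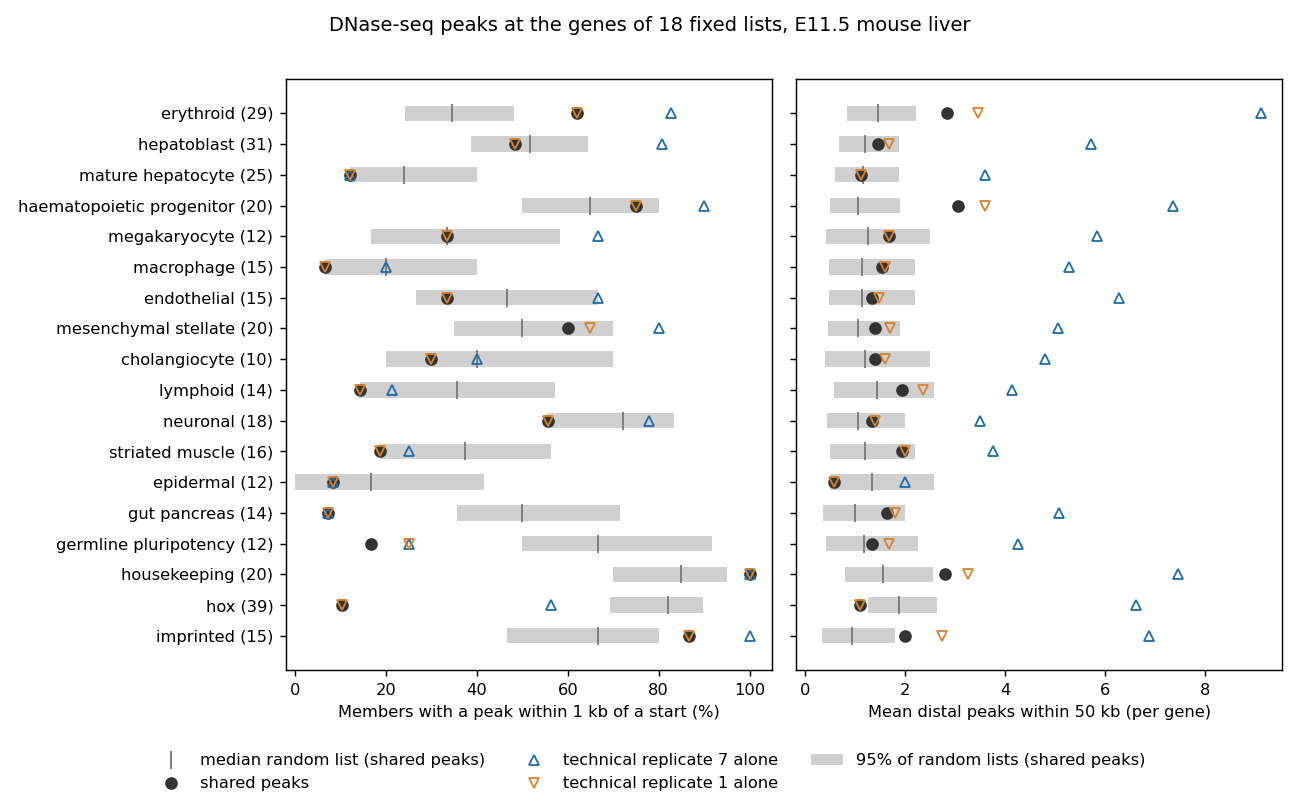
Left, share of each list's members with a peak within 1 kb of a start (%); right, mean number of distal peaks within 50 kb per gene. Filled circles are shared peaks and triangles each library alone. Grey bars are the central 95% of 10000 matched random lists of protein-coding genes, counted in shared peaks, with their median as a tick. Erythroid genes sit at 62.1% against a random median of 34.5%, and Hox genes at 10.3% against 82.1%. Triangles are not to be read against the grey bars, which hold for shared peaks.

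Distal open sites were frequent near erythroid and haematopoietic progenitor genes. Erythroid genes had a mean of 2.83 distal shared peaks within 50 kb against 1.45 in random lists (95% of lists between 0.828 and 2.21; percentile 99.925), and 25 of 29 had at least 1. These sum to 82 with a peak counted for each gene near it, and 73 peaks were distinct, since globin genes of a cluster share peaks. Zfpm1 carried 16; without it the percentile was 98.6. Progenitor genes had a mean of 3.05 with 95% of random lists between 0.5 and 1.9 (percentile 99.99), of which Lyl1 carried 20 of 61; without it the mean was 2.16 and the percentile 99.3. Housekeeping genes (2.80, percentile 99.1) and imprinted genes (mean 2, percentile 98.7) were also high, but without the member richest in distal peaks they lay at 95.04 and 96.1, inside the range. Hox genes were low in shared peaks (1.10 against 1.87, percentile 0.575) and high in technical replicate 7 alone (6.62 per gene, percentile 99.0), and within the range with a distal window of 20 kb (3.47), against lists not matched on the number of starts (27.9) and in the stronger 50% of shared peaks (26.0), so that the low call depends on the library and on these choices; Hox genes lie in clusters, and their windows overlap. Hepatoblast genes were within the range (1.45, percentile 79.6) and above it in technical replicate 7 alone (5.71, percentile 99.6), as were endothelial genes (1.33, percentile 65.4, against 6.27 and percentile 99.1). Epidermal genes, at percentile 4.29 in shared peaks, were below the range in technical replicate 7 alone (1.65) and in the stronger 50% of shared peaks (0.495). The remaining lists lay within the range in shared peaks, with striated muscle genes at 93.0, mature hepatocyte genes at 47.4, megakaryocyte at 77.0, macrophage at 79.0, mesenchymal and stellate at 82.6, cholangiocyte at 63.7, lymphoid at 82.6, neuronal at 74.6, gut and pancreas at 90.9 and germline and pluripotency at 66.2.

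At the globin clusters, shared peaks lay at the starts of Hbq1b (chromosome 11, 32286807 to 32287130) and Hbq1a (32299833 to 32300315), both theta-globin genes, and peaks of technical replicate 7 alone at the starts of Hba-x, Hbb-bt and Hbb-bs. Of these, all but Hbb-bs were chosen after their values were seen. Hba-a1, an adult alpha-globin gene, had no promoter peak in either library and 4 distal shared peaks. Its neighbourhood on chromosome 11 (32226400 to 32347298, 50 kb beyond the cluster to each side) held 9 shared peaks, 5 of them distal. Of the distal ones 2 were in introns of Nprl3 (32238407 to 32238821 and 32245508 to 32246053), a gene whose introns are known to hold the alpha-globin enhancers. Whether these 2 peaks lie at such enhancers was not tested. In this neighbourhood technical replicate 7 listed 21 peaks, 15 of them distal. They included intronic peaks of Nprl3 not listed for technical replicate 1, the strongest at 32250932 to 32251215 (density 1.07). The beta-globin cluster on chromosome 7 (103762524 to 103903216) had 1 shared peak, an intergenic one at 103860988 to 103861224, 7887 bp from the start of Hbb-y, the embryonic beta-like globin gene. Technical replicate 7 listed 14 peaks there, 12 of them distal. Its peak at the start of Hbb-bs, an adult beta-globin gene, had a density of 0.601, and Hbb-y had none at its start. Around Alb and Afp on chromosome 5 (90410897 to 90558907) technical replicate 1 listed no peak and technical replicate 7 listed 7, the strongest in an intron of Afp (90500821 to 90501039; density 1.17). Hnf4a had 2 shared intronic peaks, the stronger at chromosome 2, 163534973 to 163535245.

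**Figure D3:**
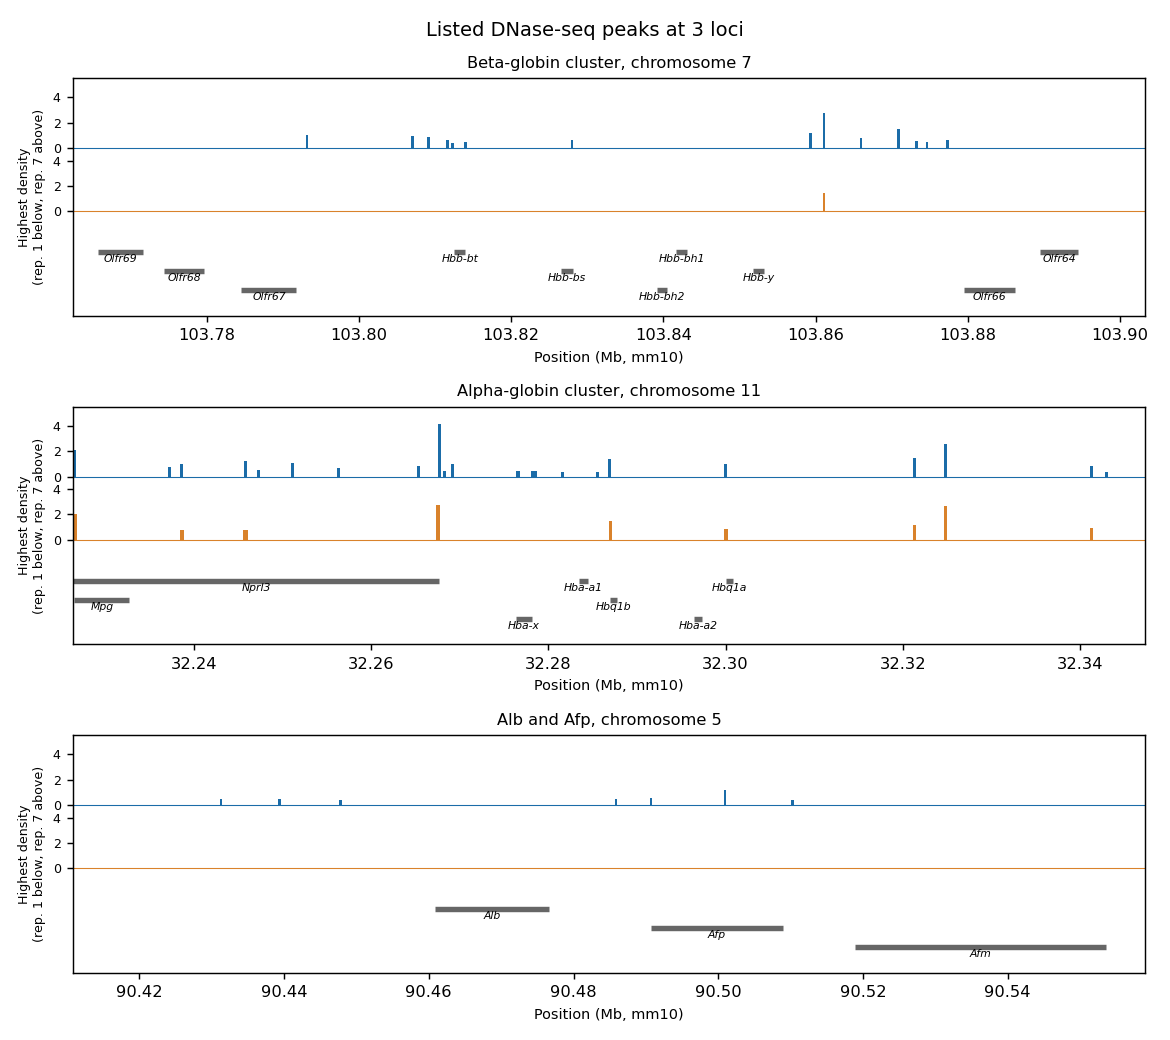
Listed peaks at the beta-globin, alpha-globin and Alb-Afp loci by position (Mb, mm10, x axis), with bar height the highest density of each peak in technical replicate 7 (blue, above) and technical replicate 1 (orange, below) and genes as grey bars. Bars are the deposited densities, drawn on the same axis scale for both libraries. The headers do not state how densities were scaled, so heights are not compared between the libraries. The beta-globin cluster shows 14 peaks in technical replicate 7 and 1 in technical replicate 1, and the Alb-Afp locus 7 and none.

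The protein-coding genes with the most distal shared peaks within 50 kb were Bcor and Nacc1 with 22 each, Arhgap23 and Tmem107 with 18, Zfpm1 with 16, Fcgr3 and Thra with 15, Sept9 with 14, and Gm11444 and Zfp184 with 13. Nacc1 and the progenitor gene Lyl1 are neighbours on chromosome 8, and the 50 kb windows around their starts overlap. The median gene had 1, and 10365 genes (47.2%) had none. By mean density rank over both libraries, the highest distal shared region lay in an exon of Lars2 on chromosome 9 (123461890 to 123462123, densities 28.0 and 24.1). It is also taken up below among the pile-ups of technical replicate 7, and regions were not filtered for pile-ups. The others of the 5 highest were intergenic on chromosome 8 (3754355 to 3754564), intergenic on chromosome X (143482965 to 143483155; densities 101 and 10.5, 1 of the pile-ups of technical replicate 7), in an intron of Jarid2 on chromosome 13 (44869524 to 44869747) and intergenic on chromosome 1 (122357112 to 122357313).

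Of the motifs searched, the binding site of CTCF, the insulator protein, had the highest ratio to flanks in distal shared peaks. Its consensus was found in 17.96% of 14325 distal windows and 0.0512% of 25391 flanking windows, a ratio of 351 (95% interval 203.5 to 605), and 227 in technical replicate 7 alone. NRF1 (13.3, from 4.77 in technical replicate 7 alone to 20.04 in technical replicate 1 alone) and NFI (8.86, from 5 peaks; intervals including 1 with flanks matched on GC content and with flanks at 5 kb) came next. Among motifs of red cell regulators, the composite of an E-box and GATA bound by TAL1 and GATA1 had a ratio of 8.80 (6.57 to 11.8; 5.38 in technical replicate 1 alone and 14.3 with matched GC), the NFE2 site 5.23 (3.15 to 8.68) and the CACCC box of KLF factors 2.38 (2.23 to 2.53), which fell to 1.23 (1.14 to 1.32) with matched GC. The short GATA motif alone was no more frequent than in flanks (20.9% against 20.8%; ratio 1.00, 0.965 to 1.04). That value depends on the library and on base composition: it was 1.25 in distal peaks of technical replicate 7, 0.858 in those of technical replicate 1, 0.762 in the stronger 50% of shared distal peaks, and 1.68 against flanks matched on GC content, the distal windows having 56.3% GC and the flanks 47.3%. The site of FOXA factors had a ratio of 0.802 (0.560 to 1.15), 1.59 in technical replicate 7 alone, 0.673 in technical replicate 1 alone and 2.77 with matched GC, and that of HNF4 1.22 (0.783 to 1.897), 1.87 in technical replicate 7 alone. The SP (6.16; 1.97 with matched GC), NFY (1.33), ETS (2.9996; 1.42 in technical replicate 1 alone, an interval including 1), PU.1-type ETS (1.32; 2.24 in technical replicate 7 alone, and intervals including 1 with matched GC, at 1.04, in the stronger 50% of shared peaks, at 1.03, and within 50 bp of the centre, at 1.25), MYOD-type E-box (1.87; 1.25 with matched GC) and AP-1 (1.297; 1.18 in the stronger 50% of shared peaks, 0.944 to 1.48) motifs were also above 1. The relaxed C/EBP (0.814), TEAD (0.823), OCT (0.685), SOX (0.630) and p63 (0.620) motifs were below 1, but with flanks matched on GC relaxed C/EBP rose to 1.48, OCT to 1.72 and SOX to 1.17, and TEAD was at 1.02 in technical replicate 7 alone and p63 at 1.29 in the stronger 50% of shared peaks. The RUNX (1.0455), strict C/EBP (3.54), HNF1 (2.95) and HNF6 (1.06) motifs had intervals that included 1. In technical replicate 7 alone all 4 lay above 1, RUNX at 1.57 (1.46 to 1.68), strict C/EBP at 5.79 (2.47 to 13.6), HNF1 at 2.66 (1.46 to 4.85) and HNF6 at 1.25 (1.053 to 1.48), and RUNX did so with matched GC (1.60, 1.24 to 2.08). The REST site was in 8 of 14325 distal windows and in 0 of the flanks, so no ratio was formed. At transcription starts the order differed: NRF1 had a ratio of 215 (53.5 to 863), CTCF 29.9 (18.1 to 49.4), SP 23.9 and ETS 19.4, and GATA 0.325 (0.309 to 0.343). Flanks matched on GC were not used at starts, so base composition may explain these values in part.

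**Figure D4:**
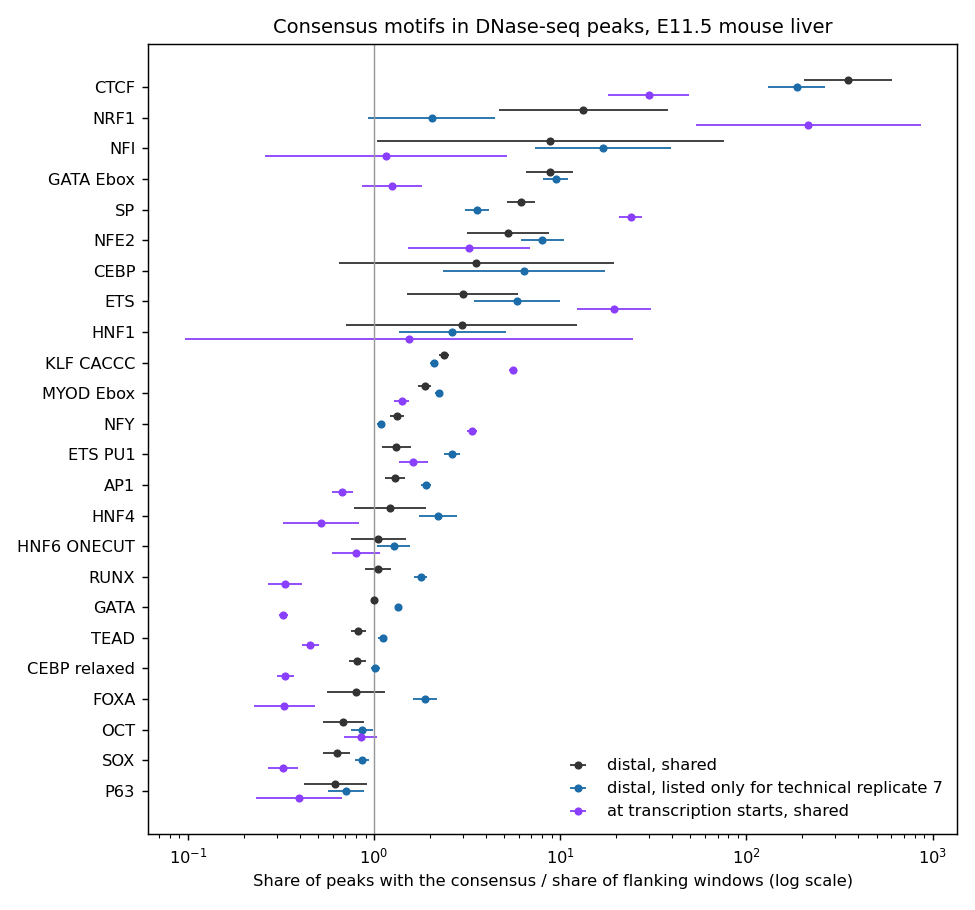
Ratio of the share of peaks with each consensus to the share of flanking windows (log x axis) for distal shared peaks (black), distal peaks listed only for technical replicate 7 (blue) and shared peaks at transcription starts (purple), with 95% intervals for counting error. CTCF has the highest ratio in distal shared peaks, at 351, and NRF1 at starts, at 215.

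Footprints had a median width of 9 bp in both libraries. Technical replicate 7 had 107626, of which 86.6% (86.4 to 86.9) lay inside its peaks, and technical replicate 1 had 219621, of which 64.0% (63.8 to 64.2) did; the lists come from different processing. Of the footprints of technical replicate 7, 45.4% overlapped one of technical replicate 1. In technical replicate 7, CTCF sites were 384-fold (242 to 610) more frequent at footprints than 100 bp away in the same peaks, NRF1 sites 90.6-fold, NFI sites 17.85-fold (5.54 to 57.5), strict C/EBP sites 14.6-fold (3.45 to 61.8), SP sites 8.88-fold, ETS sites 5.21-fold, CACCC boxes 4.55-fold, NFE2 sites 4.40-fold, HNF1 sites 4.26-fold (1.40 to 12.9) and the GATA and E-box composite 3.68-fold (2.91 to 4.66). The short GATA motif was less frequent at footprints (0.822-fold, 0.786 to 0.860), as was that of FOXA (0.451-fold, 0.297 to 0.685), and in technical replicate 1 as well (0.638-fold and 0.362-fold). Moved points were not matched to footprints on base composition, on which the GATA and FOXA ratios in distal peaks depended. It may explain the footprint ratios in part, and avoidance of these sites is not shown. In technical replicate 1 the composite was at 1.48-fold (1.08 to 2.02), CTCF at 119-fold, NRF1 at 21.2-fold, strict C/EBP at 3.20-fold (1.06 to 9.66) and NFE2 at 2.56-fold; the interval of NFI included 1, and HNF1 sites were in 0 of the footprints. Against points moved by 50 bp in technical replicate 7, CTCF was at 115-fold, NRF1 at 55.0-fold, NFI at 11.7-fold, HNF1 at 9.31-fold and NFE2 at 2.78-fold. The same move in technical replicate 1 gave 64.5-fold for CTCF and 39.3-fold for NRF1. The intervals of NFE2 (1.25-fold, 0.755 to 2.07) and strict C/EBP (2.71-fold, 0.984 to 7.45) then included 1. That of NFI (8.13-fold, 1.03 to 64.1) no longer did.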

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

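The tests of list length and of the pile-ups were chosen only after their results were seen. A signal appeared in a deposited list the comparisons above did not use. It comes from the same library, technical replicate 1, at a looser threshold than its peaks, and is not independent of them. Among the 46250 peaks listed only for technical replicate 7, 51.1% (95% exact interval 50.7 to 51.6, counting error only) held at least 1 position with an FDR below 0.05 in the separate position list of technical replicate 1, against 2.11% of equal windows moved by 20 kb. The share was 44.0% for distal peaks and 80.2% for peaks at transcription starts. Of the same peaks, 38.6% overlapped a peak of an earlier processing of technical replicate 1.

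The list of technical replicate 7 held 2.03 times as many peaks as that of technical replicate 1, with a lower share at transcription starts. This ratio holds for the lists used. Those of an earlier processing of technical replicate 1 held 62288, 99983 and 106208 peaks, against 86036 in the list used for technical replicate 7. The number of peaks therefore also depends on the list and its processing. List length alone is argued against by the longer of the lengths compared: among the 20000 strongest peaks of each, the share at starts was 12.0 percentage points (11.1 to 12.9) higher in technical replicate 1, and among the 42422 strongest 12.98 points higher, though it was 2.65 points higher among the 10000 strongest and differed by -0.580 points among the 5000 strongest. A shallower technical replicate 1 that misses weak sites open in it too predicts a share above that of moved windows. The 51.1% above met this, though it leaves 48.9% of windows without such a position. The moved windows were not chosen for nearness to open chromatin. Other causes could therefore also put the share above theirs, and the test does not single out depth. The splitting of promoters into several peaks stays open as a part: after pooling peaks within 500 bp the difference was 5.50 points (4.53 to 6.47), and pooling also moves both lists to other ranks. A difference of sequencing batch cannot be separated from the library, and no biological explanation was tested, since both libraries come from 1 sample.

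Technical replicate 7 also had pile-ups far above its other peaks. The highest, inside Afg1l on chromosome 10 (42342428 to 42342602), reached a density of 4760, and the next, on chromosome 13 (49219505 to 49219680), reached 260, whereas the fifth highest peak reached 21.0. In technical replicate 1, 0 peaks of the 4 lists searched overlapped either, which argues against an open region present in the sample at that height; within 500 bp, 3 positions under the FDR threshold lay near the first and 0 near the second. The third, on chromosome X, reached 101 and had a peak of density 10.5 in technical replicate 1. A further 1, in Lars2 on chromosome 9, reached 28.0 and had a peak of density 24.1 in technical replicate 1, the highest there. The source of the excess was not tested.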

How the results depend on the processing

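Shares, ranks and calls were recomputed with 1 choice changed at a time. Windows centred on the summit, lists without their member richest in distal peaks genes that share peaks taken as 1 locus and random genes set against each of the erythroid and hepatoblast lists were chosen after seeing the data. Over the alternatives, 85 promoter percentiles, 112 distal percentiles, 155 motif ratios and 60 footprint values kept their direction and side of the threshold or stayed within the interval. Of the counts of distal peaks of single named genes, 112 moved and 132 did not; these are not listed. The shares of technical replicate 1's and 7's peaks found in the other library, 89.9% and 46.2%, became 65.9% and 32.5% for reciprocal overlap of at least 50%, 73.6% and 73.3% for both lists at the length of the shorter, 78.1% and 77.8% for strongest peaks at 50% of the shorter list's length, 89.1% and 45.1% for longer peak lists and 87.7% and 36.9% for hotspots. Under smoothed peak height, the Spearman correlation of 0.821 became 0.756. Under shared peaks with reciprocal overlap of at least 50%, the Spearman correlation of 0.821 became 0.843. Against unmatched random lists, the promoter percentile became 62.3 for erythroid, 0 for mature hepatocyte, 0 for macrophage, 2.495 for endothelial, 0.055 for striated muscle and 0.005 for epidermal. For stronger 50% of the shared peaks, the promoter percentile became 1.60 for hepatoblast, 0.180 for endothelial, 14.3 for lymphoid, 0 for neuronal and 37.4 for imprinted. For promoter window of 2500 bp, the promoter percentile became 1.17 for mature hepatocyte and 6.57 for lymphoid. For promoter window of 500 bp, the promoter percentile became 3.19 for lymphoid, 0.08 for neuronal and 2.24 for striated muscle. For stronger 50% of the shared peaks, the distal percentile became 0.495 for epidermal and 26.0 for hox. Without the member with the most distal peaks, the distal percentile became 2.47 for epidermal, 95.04 for housekeeping and 96.1 for imprinted. For distal window of 20 kb, the distal percentile became 94.8 for housekeeping and 3.47 for hox. Against unmatched random lists, the distal percentile became 27.9 for hox and 92.3 for imprinted. For distal window of 100 kb, the distal percentile became 94.7 for imprinted. For motif window of 50 bp, the motif ratio in distal peaks became 1.07 for GATA and 1.25 for ETS PU1. For motif window of 150 bp, the motif ratio in distal peaks became 0.939 for GATA. For flanks at 5 kb, the motif ratio in distal peaks became 0.936 for GATA and 4.73 for NFI. For stronger 50% of the shared peaks, the motif ratio in distal peaks became 0.762 for GATA, 1.18 for AP1, 1.03 for ETS PU1, 1.16 for OCT and 1.29 for P63. For flanks matched on GC, the motif ratio in distal peaks became 1.68 for GATA, 1.60 for RUNX, 1.04 for ETS PU1, 2.77 for FOXA, 1.48 for CEBP relaxed, 3.93 for NFI, 0.905 for TEAD, 1.72 for OCT, 1.17 for SOX and 0.647 for P63. With the longer footprint list, 73.9% of footprints of technical replicate 7 lay inside peaks. For longer footprint list, the footprint ratio became 1.25 for AP1, 1.14 for RUNX and 1.504 for HNF4. For footprints moved by 50 bp, the footprint ratio became 0.719 for ETS PU1 and 1.20 for HNF6 ONECUT. Still called but moved by over 1.5 times, the motif ratio in distal peaks was 4.75 for GATA Ebox, 15.5 for NFI, 160 for CTCF, 7.68 for NRF1 under motif window of 150 bp and 5.38 for GATA Ebox, 20.04 for NRF1 under technical replicate 1 alone. The ratio was likewise 5.65 for GATA Ebox, 20.7 for ETS, 2.01 for NFY, 29.3 for NRF1 under stronger 50% of the shared peaks and 14.3 for GATA Ebox, 1.23 for KLF CACCC, 1.97 for SP under flanks matched on GC. The ratio was likewise 8.24 for NFE2 under motif window of 50 bp and 2.24 for ETS PU1, 4.66 for ETS, 15.8 for NFI, 227 for CTCF, 4.77 for NRF1 under technical replicate 7 alone. The ratio was likewise 9.74 for SP, 28.4 for NRF1 under flanks at 5 kb. Still called but moved by over 1.5 times, the footprint ratio was 1.48 for GATA Ebox, 2.56 for NFE2, 3.20 for CEBP, 119 for CTCF, 21.2 for NRF1, 0.528 for SOX, 0.235 for P63 under technical replicate 1 alone and 2.78 for NFE2, 9.31 for HNF1, 11.7 for NFI, 115 for CTCF, 55.0 for NRF1 under footprints moved by 50 bp. The ratio was likewise 31.2 for NFI, 220 for CTCF, 0.550 for P63 under longer footprint list. Leaving out a library moved the share at transcription starts between 38.4% and 61.9%. Leaving out a library, the promoter percentile ranged from 28.8 to 99.9 for hepatoblast, 0.220 to 2.38 for mature hepatocyte, 86.1 to 99.0 for haematopoietic progenitor, 40.5 to 98.6 for megakaryocyte, 92.4 to 98.9 for mesenchymal stellate, 1.86 to 2.76 for lymphoid. Leaving out a library, the distal percentile ranged from 81.4 to 99.6 for hepatoblast, 63.1 to 99.1 for endothelial, 1.65 to 3.01 for epidermal, 0.190 to 99.0 for hox. Leaving out a library, the motif ratio in distal peaks ranged from 0.858 to 1.25 for GATA, 0.952 to 1.57 for RUNX, 1.42 to 4.66 for ETS, 0.673 to 1.59 for FOXA, 1.20 to 1.87 for HNF4, 0.436 to 2.66 for HNF1, 1.74 to 5.79 for CEBP, 0.811 to 0.958 for CEBP relaxed, 1.11 to 1.25 for HNF6 ONECUT, 0.832 to 1.02 for TEAD. Without technical replicate 7, the footprint ratio became 0.642 for AP1, 0.664 for RUNX, 0.792 for ETS PU1, 1.19 for HNF6 ONECUT, 7.69 for NFI, 0.928 for MYOD Ebox. The promoter calls for Hox, gut and pancreas, germline and pluripotency and housekeeping genes and the distal calls for erythroid and haematopoietic progenitor genes held under each alternative run for them. Leaving out the member richest in distal peaks can only lower a mean, so that it tests high lists and says nothing for the low side of the epidermal list. Each library alone lists more regions than the shared set, and matched flanks have another base composition by construction; otherwise the cause was not tested. The shared lists hold no site that either library did not list; how far depth limited either list was not measured apart from the density step.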

Other observations

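The test of motifs near gene lists in technical replicate 7 was added after that in shared peaks had decided nothing, and a minimum motif share of 5% of peaks was chosen after the values of both were seen, as were the test with genes that share peaks taken as 1 locus and that against random genes. Distal peaks listed only for technical replicate 7 held the following motifs. Against flanks, the ratio was 186 for CTCF, 16.9 for NFI, 9.44 for the GATA and E-box composite, 8.02 for NFE2, 6.39 for strict C/EBP, 5.85 for ETS, 2.63 for PU.1-type ETS, 2.23 for the MYOD-type E-box, 2.20 for HNF4, 1.899 for AP-1, 1.88 for FOXA, 1.78 for RUNX and 1.35 for GATA, and the relaxed C/EBP motif was at 1.02 with an interval that included 1. SP was at 3.59, HNF1 at 2.63 (1.36 to 5.11), the CACCC box at 2.09, HNF6 at 1.27, TEAD at 1.11 and NFY at 1.09. NRF1 was at 2.04 with an interval that included 1. The OCT (0.859), SOX (0.865) and p63 (0.704) motifs were below 1. Distal shared peaks had 1.22 for HNF4, 0.802 for FOXA, 1.0455 for RUNX and 1.00 for GATA. The difference between these sets was not tested, and flanks matched on GC were not used for this set.

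A hypothesis was that sites of red cell regulators concentrate near erythroid genes and those of liver regulators near hepatoblast genes. In distal peaks of technical replicate 7 within 50 kb, GATA was found in 41.7% of 211 peaks near 29 erythroid genes and 22.6% of 155 peaks near 31 hepatoblast genes, a difference of 22.5 percentage points when a peak near several genes of a list is counted for each (two-sided permutation of genes between the lists, p = 5e-05, Benjamini-Hochberg adjusted p = 0.0003 over 6 motifs). Genes of a cluster, such as the globin genes, share peaks, so that this p is too small; with genes that share peaks taken as 1 locus and each peak counted once, the difference was 19.1 points over 24 and 27 loci (permutation p = 0.00156, adjusted p = 0.00936). Over all distal peaks of technical replicate 7 the share was 29.6%, between those of the lists. Each list by locus was therefore also set against 100000 random lists of protein-coding genes matched on the number of distal peaks: erythroid genes, at 41.7%, lay above them (median 25.8%, central 95% from 18.8% to 33.5%; two-sided permutation test by drawing matched genes, p = 0.0001, adjusted p = 0.0006), and hepatoblast genes, at 22.6%, within them (median 27.5%, 19.8% to 35.6%; p = 0.218). This is what the hypothesis predicts for GATA sites near erythroid genes, tested on 1 library of 1 sample. Neither the permutation nor the random genes, here or in shared peaks, were matched on the base composition of the peaks. The GATA ratio in distal shared peaks depended on it (1.00 against flanks, 1.68 with matched GC). A difference in base composition between the peaks near the 2 lists therefore stays open. In distal shared peaks GATA was in 34.2% of 73 peaks and 17.9% of 39, a difference of 11.7 points gene by gene (permutation p = 0.264, adjusted p = 0.399) and of 16.3 by locus (permutation p = 0.139, adjusted p = 0.416), which decides nothing; against random genes the 34.2% lay above the central 95% (9.52% to 29.7%; p = 0.00730, adjusted p = 0.0438).

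The other motifs gave no decision. The CACCC box differed by 3.48 points in technical replicate 7 (permutation p = 0.405) and 5.18 points in shared peaks (permutation p = 0.452). The liver motifs were too rare for a call, below 5% of the peaks of both lists pooled, a peak counted for each gene near it (at most 2.95%, for the relaxed C/EBP motif in technical replicate 7). Without that minimum, set after the values were seen, FOXA and the relaxed C/EBP motif in technical replicate 7 would have been called gene by gene, but not by locus (adjusted permutation p = 0.163 and 0.0995), and neither was above random genes near hepatoblast genes (adjusted p = 0.935 and 0.851). The relaxed C/EBP motif was in 3 and 8 peaks of technical replicate 7 (difference -4.51 points, permutation p = 0.00382, adjusted p = 0.0115) and differed by -3.22 points in shared peaks. FOXA was in 0 and 1 peaks (-0.565 points, permutation p = 0.0105, adjusted p = 0.0210) and in 0 and 0 shared peaks (0 points). HNF4 was in 1 and 2 peaks (-0.751 points) and in 0 and 1 shared peaks (-2.22 points, permutation p = 0.0365, adjusted p = 0.219). In simulations with no difference, 7.87% of tests fell below 0.05 when the motif was in 1% of peaks and 4.75% when it was in 5%. A score statistic tried after these values were seen gave permutation p = 0.00011 for GATA and 0.0105 for FOXA in technical replicate 7.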
